A study of Macaca mulatta with 30 samples.

How the data were processed

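Total RNA from snap-frozen lung of 11 rhesus macaques was sequenced in 30 libraries, 1 per lung region. The groups were 3 unirradiated controls with 2 regions each, 4 irradiated non-survivors with 3 regions each and 4 irradiated survivors with 3 regions each. RNA came from bead-homogenised tissue by QIAzol and RNeasy extraction with DNase treatment, and the labels say only that library preparation followed Illumina's standard steps. Per the labels, the authors checked reads with FastQC, aligned them with STAR, assigned them to genes with featureCounts and analysed them with limma, and no versions are given. Genome build, annotation release and strand setting are not given in the sources used here.

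The deposited table holds raw read counts per gene, without normalisation, for 30246 gene IDs, and the totals differ between libraries. The deposited annotation gives each gene's name, chromosome, biotype and other values, its start and end in base pairs, on a build that is not named. Symbols are those of this annotation. A reference table of gene names was used where the annotation gave only an ID or a spreadsheet date. It was also used where its symbol, but not the annotation's, was in a gene list described below. Of the 30246 IDs, 15769 were in the reference table, and 1306 have another symbol there. Named genes with such a conflict are called uncertain, but list members renamed from the reference table are not. Libraries held 4031692 to 11622356 counts. Counting intervals and floors (3 counts over a group where a group had none, and 95% exact Poisson intervals) use counts pooled by group. They cover counting error only and leave out the spread between animals. Reads also carry no molecular identifiers.

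Regions of 1 animal are not independent, so counts were summed over regions and the animal was the replicate, with 8879557 to 30286607 counts per animal. Genes passing edgeR's filterByExpr were kept, 17504 in all. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model with robust estimation, the 3 groups in 1 fit, under R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The 3 comparisons were non-survivor with control, survivor with control, and non-survivor with survivor, each two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled totals, and log2 values per animal use a prior count of 2. Standard errors of log2 fold changes come from the edgeR F statistic. Genes called in both irradiated groups were set beside 50 simulations in which both groups were unchanged and shared 3 simulated controls.

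Before the data were examined, 30 gene lists of lung cell types, tissue contaminants and pathways were fixed, and 29 had the 4 tested members that a list test needed. Lists were tested with limma's camera on the edgeR fit with a preset correlation of 0.01, adjusted over the 29 lists. Beside it stand camera with the correlation estimated for each list, and fry. The rule for named genes was also fixed then. It takes the 8 genes with the largest and the 8 with the most negative log2 fold change past the threshold, with a symbol, a mean of at least 2 CPM and no overlap between the animals of the groups. It also takes up to 4 members with the smallest p from each list described. Members outside that rule that stand behind a count of 5 or fewer were named after their values were seen.

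The alternatives tried were other scalings, other filters, DESeq2, limma-voom, single libraries with or without the animal as a random block, each form of the library labels alone or as a term, fewer regions, libraries without an R in the label, a replicate block, the compared groups alone, age at irradiation as a covariate or held at 1 value, and leaving out each animal. Calls were tested on simulated data of the same sizes with 100 genes changed by 2-fold and 100 by 4-fold. With edgeR, 47%, 51% and 57% of the 2-fold changes were found in the 3 comparisons, and 82%, 78% and 80% of the 4-fold changes, with 7.86%, 7.19% and 6.80% false calls. With DESeq2, false calls were 20.4%, 24.9% and 23.5%, and with limma-voom 3.76%, 4.62% and 7.38%. Each comparison had 1 simulated set, drawn with edgeR's own dispersions. Fewer genes were changed in it than were called in the data, so these rates need not hold for the data. Pairs of libraries were checked for copies by the chi-square per degree of freedom between their counts over 14683 genes with at least 300 counts in total. The lowest value over 435 pairs was 3.20, within 1 animal, so no library was a copy of another. An empty column of the deposited table was not used.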

Results

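Lung RNA was sequenced from 11 rhesus macaques in 3 groups: 3 unirradiated controls, 4 irradiated animals that did not survive and 4 irradiated animals that survived. The unit of comparison is the animal, with read counts summed over its 2 (control) or 3 (irradiated) lung regions. Total counts per library were 4031692 to 9537806 in controls, 4324505 to 11622356 in non-survivors and 4141038 to 11021386 in survivors. Irradiated lungs were sampled where they were affected and control lungs at random, so the kind of region differs with irradiation. Ages at irradiation on the labels were 2.5 to 2.83 years in controls, 3.76 to 4.76 in non-survivors and 4.76 to 5.76 in survivors. The unirradiated controls have such an age too, and what it marks for them is not known here. By these labels, each comparison with controls is also one of ages. Radiation dose and the time from irradiation to tissue collection are not in the labels.

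The first principal component, with 35.7% of the variance, separated the non-survivors (13.6 to 65.9) from all controls (-57.1 to -43.0) and survivors (-34.0 to 12.2). Region 2 of non-survivor 2 stood apart on the second component, at 60.3. Mitochondrial genes took 2.30% ± 0.54 (SD, n = 4) of counts in non-survivors, 1.5% ± 0.14 (n = 3) in controls and 1.49% ± 0.25 (n = 4) in survivors. The non-survivor mean was above both others by more than the SD of any group, and this difference was not tested. Short genes annotated as miRNA took from 0.435% to 14.5% of the counts of a library. Over all genes, regions of 1 animal had an estimated correlation of 0.36 (jackknife SE 0.0562), and 0.27 without the filter on low counts.

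**Figure D1:**
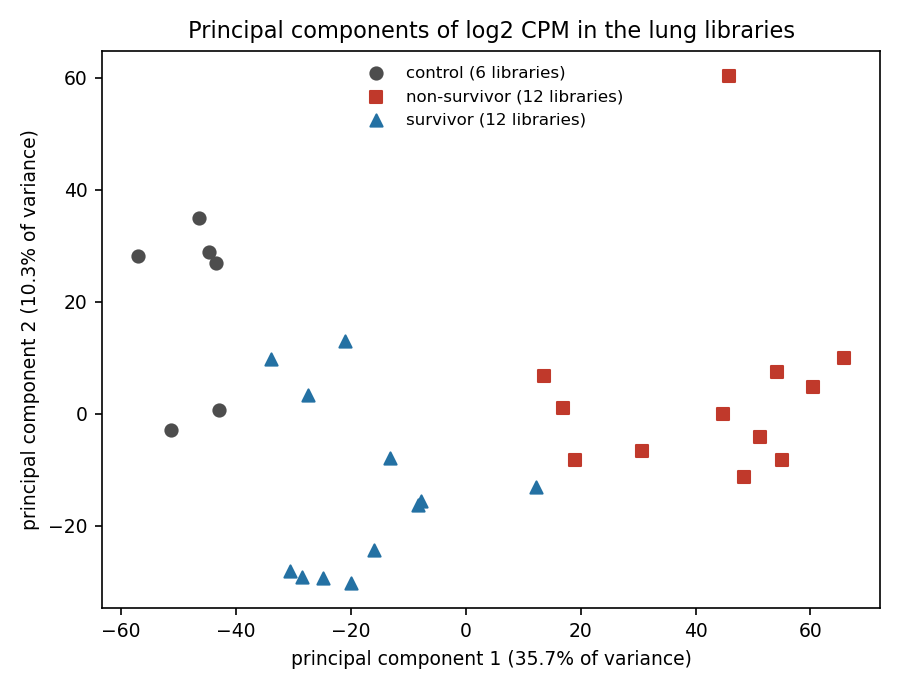
Principal components 1 and 2 of log2 CPM for the 30 lung libraries, 1 point per library, with the share of variance on each axis. The 12 non-survivor libraries lie at 13.6 or more on the first component, and the 6 control libraries at -43.0 or less.

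The comparison of non-survivors with controls asks what differs in irradiated lung of animals that died. Lung of non-survivors had higher levels of many p53 targets, macrophage genes, chemokines, matrix proteases and genes of stressed alveolar epithelium, and lower levels of many endothelial genes. In these lists 14 of 19, 13 of 15, 8 of 14, 10 of 13 and 7 of 8 genes were higher and 8 of 13 endothelial genes lower, and with an estimated correlation between genes no list passed (adjusted p = 0.147 to 0.190). CDKN1A, a p53-induced inhibitor of the cell cycle (ENSMMUG00000003210, chromosome 4, 36439098 to 36447656), averaged 23.6 ± 1.76 CPM (SD, n = 3) in controls and 280.4 ± 68.4 CPM (n = 4) in non-survivors, a log2 fold change of 3.57 ± 0.28 (SE, adjusted p = 4.31e-05). SPP1, which encodes osteopontin (ENSMMUG00000008793, chromosome 5, 80941184 to 80948949), went from 9.73 ± 0.338 CPM (SD, n = 3) to 123 ± 40.5 CPM (n = 4), a log2 fold change of 3.66 ± 0.29 (SE, adjusted p = 4.31e-05). CLDN5, a tight junction protein of endothelium (ENSMMUG00000016935, chromosome 10, 63571666 to 63573958), went from 167 ± 10.3 CPM (SD, n = 3) to 49.7 ± 14.1 CPM (n = 4), a log2 fold change of -1.75 ± 0.18 (SE, adjusted p = 1.42e-04). In edgeR, 5917 of 17504 tested genes changed, 3102 higher and 2815 lower, and 1963 of them by at least 2-fold. All 3 genes lay outside the range of the other group in every animal, as the plot of CPM by animal shows.

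**Figure D2:**
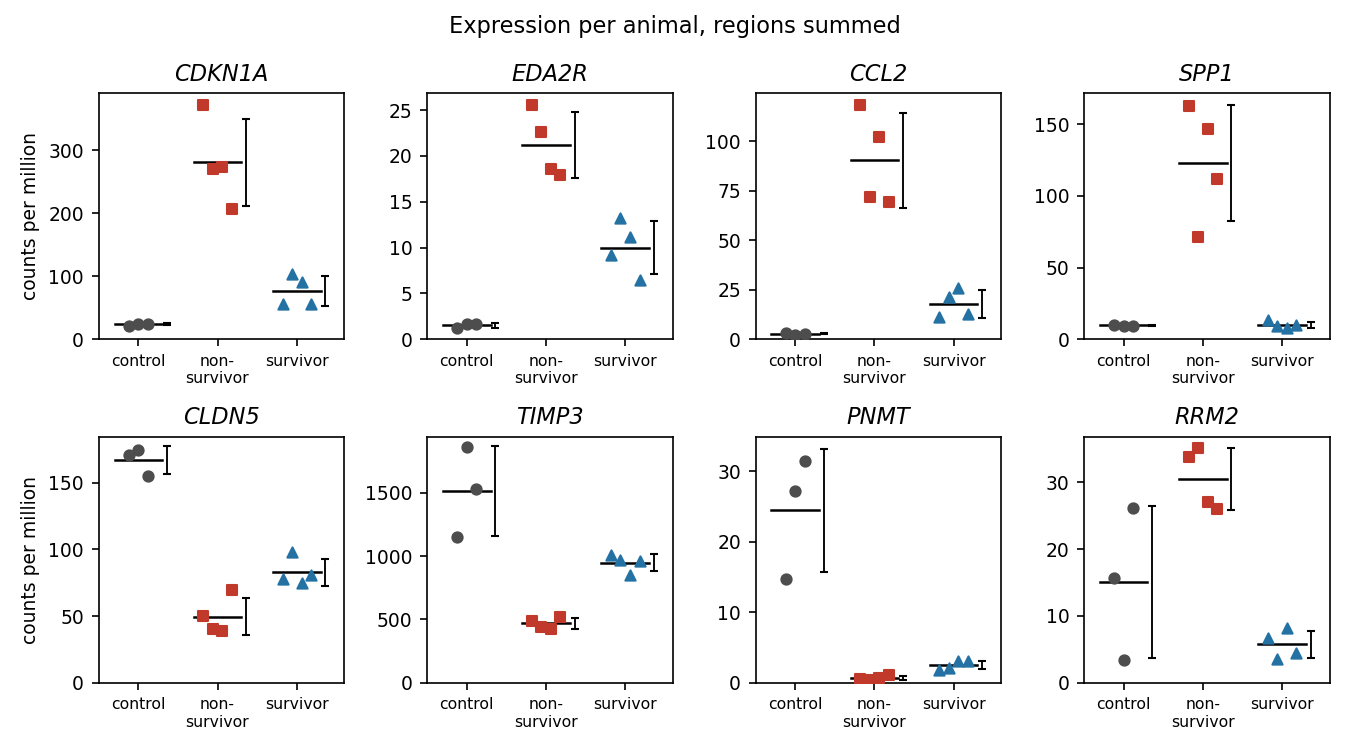
CPM of 8 genes in each of 11 animals, regions summed, on linear axes from 0, with the group mean (line) and SD (bar). CDKN1A averaged 280.4 CPM in non-survivors, 76.4 CPM in survivors and 23.6 CPM in controls.

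Among 19 p53 targets, 14 were higher and 2 lower in non-survivors (14 and 2 adjusted over the list alone). The list test gave adjusted p = 3.57e-10, and adjusted p = 0.147 with an estimated correlation. EDA2R, a receptor of ectodysplasin, rose by 3.78 ± 0.28 (log2, SE), ZMAT3 by 2.34 ± 0.22 and TNFRSF10B, a death receptor, by 2.05 ± 0.20, and the lower members were SESN1 (-0.64) and XPC (-0.38). Of 9 senescence-associated genes, 8 were higher (8 adjusted over the list alone), among them GDF15 (2.99 ± 0.29), IL6 (3.05 ± 0.41) and MMP3 (6.04 ± 1.04). That list had adjusted p = 1.73e-07, and adjusted p = 0.147 with an estimated correlation. Of 14 NF-kB cytokine and chemokine genes, 8 were higher and NFKBIA (-0.52) lower (8 and 1 adjusted over the list alone), with adjusted p = 3.69e-05 and adjusted p = 0.190 with an estimated correlation. CCL2, the main monocyte attractant, rose by 5.05 ± 0.38, SOCS3 by 2.38 ± 0.30 and PTGS2, the inducible prostaglandin synthase, by 1.95 ± 0.29. Of 8 genes of the NRF2 and oxidative stress list, 5 were higher (5 adjusted over the list alone), among them SRXN1, SLC7A11, HMOX1 and GCLC, with adjusted p = 0.00395 and adjusted p = 0.190 with an estimated correlation. Of 8 immediate early genes, which also respond to tissue handling, 6 were higher (6 adjusted over the list alone), ATF3 by 1.65 ± 0.24 and FOSB by 2.30 ± 0.48, with adjusted p = 0.00606 and adjusted p = 0.348 with an estimated correlation.

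Of 22 collagen and matrix genes, 12 were higher and DCN (-0.56) lower (15 and 1 adjusted over the list alone), with adjusted p = 3.72e-05 and adjusted p = 0.238 with an estimated correlation. COL1A1, a chain of type I collagen, rose by 1.94 ± 0.31, THBS2 by 1.84 ± 0.27 and VCAN by 1.31 ± 0.23; LOXL2, also counted, is uncertain, because the reference table names its ID otherwise. Of 13 matrix proteases and inhibitors, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), with adjusted p = 1.21e-04 and adjusted p = 0.190 with an estimated correlation. PLAUR, the urokinase receptor, rose by 2.41 ± 0.30, PLAU by 2.20 ± 0.29 and MMP14 by 1.23 ± 0.17, and TIMP3, a protease inhibitor, fell by 1.69 ± 0.15. Of 8 genes of stressed or transitional alveolar epithelium, 7 were higher (8 adjusted over the list alone), including AREG (3.96 ± 0.61), SFN (3.46 ± 0.55) and LGALS3 (1.83 ± 0.24), with adjusted p = 8.92e-06 and adjusted p = 0.190 with an estimated correlation. KRT17, also counted, is uncertain for the same reason as LOXL2.

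Of 13 endothelial genes, 8 were lower and 0 higher (10 and 0 adjusted over the list alone), with adjusted p = 3.72e-05 and adjusted p = 0.190 with an estimated correlation. TEK, the angiopoietin receptor, fell by 0.90 ± 0.16, FLT1 by 0.66 ± 0.10 and TIE1 by 0.62 ± 0.10. Of 15 macrophage and monocyte genes, 13 were higher (13 adjusted over the list alone, and 1 lower), with adjusted p = 1.98e-10 and adjusted p = 0.147 with an estimated correlation. TREM2, a lipid receptor of macrophages, rose by 3.55 ± 0.33, VSIG4 by 1.83 ± 0.25 and APOE by 1.77 ± 0.21. For 10 ciliated cell genes the list test passed downward (median -1.34, adjusted p = 0.0358, adjusted p = 0.614 with an estimated correlation), although 0 members passed in edgeR, 2 had an unadjusted p under 0.05, and 2 passed in DESeq2 and 5 in limma-voom. That adjusted p was 0.0581, 0.0540, 0.0595 or 0.0599 without control 3 or non-survivor 1, 3 or 4, and 0.825 in the hyphen form. Non-survivor 2, with a list mean of 3.32 log2 CPM, lay within the controls (2.76 to 3.54), and the other non-survivors were at 0.419 to 0.848. The red blood cell list had 2 of 3 tested genes lower (3 adjusted over the list alone), HBB (-3.57 ± 0.65) among them, too few for a list test.

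The other lists did not pass in this comparison, and several held members in both directions. Among alveolar type 2 genes 5 of 11 were higher, with CTSH (1.72), NAPSA (1.19) and LPCAT1 (0.89), and ETV5 (-0.88) and SFTPC (-0.53) lower (adjusted p = 0.128). Among 9 alveolar type 1 genes RTKN2 (1.04), GPRC5A (0.70) and PDPN (0.90) were higher and EMP2 (-0.93), CAV1 (-0.54) and HOPX (-0.54) lower, with a median of -0.34 and a mean of 0.10 (adjusted p = 0.639). The airway list had KRT15 (2.77) higher and the secretoglobin SCGB3A1 (-4.59) lower among 8 genes. Of 10 B and plasma cell genes, MZB1 (2.98), JCHAIN (2.92) and IRF4 (1.25) were higher and CR2 (-3.13), MS4A1 (-2.06) and CD79B (-1.56) lower. Of 13 T and NK cell genes, IL7R (-1.68) and GZMA (-1.81) were lower; of 6 mast cell genes, HDC (3.66), HPGDS (1.31), MS4A2 (2.29) and CPA3 (2.01) were higher and GATA2 (-0.84) lower. Of 8 neutrophil genes, 0 passed in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05. Of 15 interferon-stimulated genes, 3 were higher, RSAD2 (1.21) and OASL among them. Of 11 hypoxia-induced genes, 6 were higher, with HK2 (2.76), and NDRG1 (-1.28), ADM (-0.80) and BNIP3 (-0.45) lower (adjusted p = 0.0530). Of 12 sterol and fatty acid genes, 2 were higher, with SREBF1 at 1.70.

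Of 14 genes of TGF-beta signalling, 6 were higher, among them INHBA (2.61), and SMAD6 (-1.28) and LTBP1 (-0.37) were lower. Among 10 smooth muscle genes TAGLN (1.39) was higher and MYLK (-0.60) and LMOD1 (-0.48) lower. In the renin-angiotensin list, AGT (2.45) was higher of 5 genes and 3 were lower, with ENPEP at -1.80 and AGTR1 at -1.53. TYMS (2.01), MCM2 (0.77) and PCNA (0.76) were the higher members of 14 cell cycle genes, whose median was -0.15 and mean 0.11. Complement had C1R (1.25) and C1S (1.02) higher, as was C2, an uncertain name, and CFD (-0.98) lower among 8. Of the tissues that a lung sample could also hold, the mesothelial marker LRRN4 (7.08 ± 0.91) rose, cartilage had ACAN (2.34) and COL11A1 (2.15) higher and CNMD (-0.94) lower, and cardiac muscle had ACTC1 (-1.29) lower and the uncertain TNNT2 (1.44) higher. Adjusted over the list alone, the higher and lower counts were 5 and 2 (type 2), 3 and 5 (type 1), 1 and 1 (airway), 3 and 4 (B and plasma), 0 and 2 (T and NK), 4 and 1 (mast), 1 and 0 (interferon), 6 and 3 (hypoxia) and 2 and 0 (sterol). They were 7 and 3 (TGF-beta), 1 and 2 (smooth muscle), 1 and 3 (renin-angiotensin), 3 and 0 (cell cycle), 5 and 1 (complement), 1 and 0 (mesothelial), 2 and 1 (cartilage) and 1 and 1 (cardiac).

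By size of change, besides GH1 and TFF1, the genes named in this comparison began with SERPINA3, an acute-phase protease inhibitor (7.58), and ATP12A, a proton pump (7.43). Next came LRRN4 (7.08), GJB2, a gap junction protein (7.07), and DCSTAMP, which acts in macrophage fusion (6.05). GH1, an uncertain name within a family of near copies, had 0 counts in controls. Its pooled counts were at least 41.2-fold higher by the lower limit of a 95% counting interval (50.9-fold against a floor of 3 counts over the group). TFF1 had 2 counts in controls and a pooled ratio of 114 (95% counting interval 31.4 to 944). Its log2 fold change of 6.43 was 5.54 without non-survivor 3. These intervals leave out the spread between animals. In non-survivors GH1 averaged 6.05 ± 5.67 CPM and TFF1 5.70 ± 5.42 CPM (SD, n = 4). Lower were MS4A15 (-6.24), SLC6A4, the serotonin transporter (-5.55), SEC14L3 (-5.36), PNMT, which makes adrenaline (-5.14), WDR72 (-4.09), FAM107A (-4.09) and RXRG (-4.05). Leaving out 1 animal moved some fold changes toward 0 by over 1.5 times: MS4A15 (-5.17), SCGB3A1 (-3.79), HBB (-2.79) and WDR72 (-2.46, adjusted p = 0.0565) without control 3. The same held for CR2 (-2.09) without control 1, and for ATP12A (6.76), COL11A1 (1.18, adjusted p = 0.105) and the uncertain KRT17 (2.17) without non-survivor 1. It moved others away from 0: ATP12A (9.20) without control 1, SERPINA3 (8.21) without control 2, FOSB (3.10) and SFN (4.16) without control 3. Also farther from 0 were SCGB3A1 (-7.18), SEC14L3 (-6.64) and WDR72 (-4.85) without non-survivor 2, and SLC6A4 (-6.87) without non-survivor 4. GJB2, MMP3 and TFF1 also moved away from 0 without control 3, which holds most or all of their few control counts. Of 109 named genes called in this comparison, 27 lost the call without some animal.

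Of the 29 lists, 9 passed upward and 2 downward, 0 with an estimated correlation (7 at an unadjusted p under 0.05), and fry passed 17. Within the forms of library label, a possible batch, 2132 (hyphen) and 2134 (underbar) genes changed, and with control 2, which has a region in each form, left out, 95.2% of 3860 and 93.1% of 4002 genes with an unadjusted p under 0.05 in 1 form had the same sign in the other (76.1% of all genes).

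**Figure D3:**
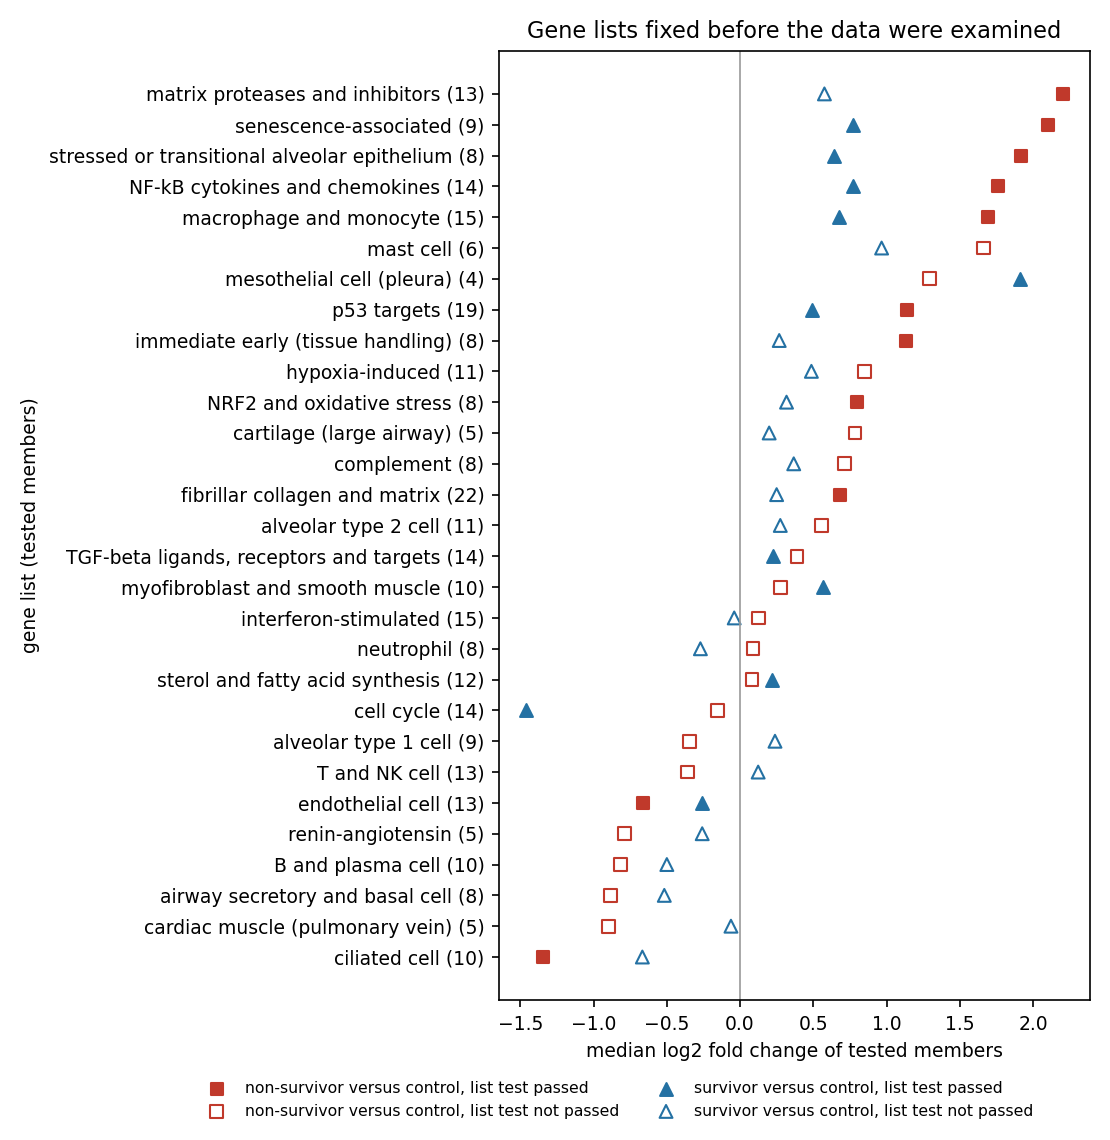
Median log2 fold change of the tested members of 29 gene lists, in non-survivors (squares) and survivors (triangles) against controls. Filled symbols passed camera with the preset correlation, and 0 lists passed with an estimated correlation. The median of the macrophage and monocyte list was 1.69 in non-survivors and 0.67 in survivors.

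The comparison of survivors with controls asks what differs in irradiated lung of animals that lived. Survivors had higher levels of some p53 targets and macrophage genes than controls, and lower levels of a few endothelial genes. These were 7 of 19, 3 of 15 and 2 of 13 genes, and with an estimated correlation each list had adjusted p = 0.535. EDA2R (ENSMMUG00000015031, chromosome X, 65480691 to 65523949) averaged 1.52 ± 0.252 CPM (SD, n = 3) in controls and 10.0 ± 2.87 CPM (n = 4) in survivors, a log2 fold change of 2.70 ± 0.28 (SE, adjusted p = 0.00208). TREM2 (ENSMMUG00000013920, chromosome 4, 40981763 to 40986454) went from 2.11 ± 0.595 CPM (SD, n = 3) to 9.09 ± 3.04 CPM (n = 4), a log2 fold change of 2.07 ± 0.33 (SE, adjusted p = 0.0103). PNMT (ENSMMUG00000001346, chromosome 16, 49763796 to 49766312) went from 24.5 ± 8.74 CPM (SD, n = 3) to 2.53 ± 0.602 CPM (n = 4), a log2 fold change of -3.28 (adjusted p = 0.00208). In edgeR, 684 genes changed, 282 higher and 402 lower, and 214 of them by at least 2-fold.

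Of 19 p53 targets, 7 were higher (11 higher and 2 lower adjusted over the list alone), with adjusted p = 1.88e-06 and adjusted p = 0.535 with an estimated correlation. CDKN1A rose by 1.69 ± 0.26, ZMAT3 by 1.33 ± 0.21 and DDB2, a sensor of DNA damage, by 0.82 ± 0.16. CDKN1A was also the member called among 9 senescence-associated genes (3 adjusted over the list alone), with adjusted p = 0.00883 and adjusted p = 0.538 with an estimated correlation. Of 15 macrophage and monocyte genes, TREM2, APOE (1.22 ± 0.21) and CSF1R (1.02 ± 0.21) were higher (8 adjusted over the list alone), with adjusted p = 1.92e-06 and adjusted p = 0.535 with an estimated correlation. CCL2 (2.70 ± 0.36) was the member called of 14 NF-kB genes (1 adjusted over the list alone), with adjusted p = 0.00172 and adjusted p = 0.535 with an estimated correlation. CLDN5 (-1.01 ± 0.18) and FLT1 (-0.41 ± 0.10) were lower among 13 endothelial genes (3 adjusted over the list alone), with adjusted p = 0.00172 and adjusted p = 0.535 with an estimated correlation. In limma-voom on single libraries with the animal as a random block, the senescence, NF-kB and endothelial lists lost the call (adjusted p = 0.122, 0.121 and 0.176).

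Among 14 cell cycle genes CCNA2 fell by 1.09 ± 0.26 (11 lower adjusted over the list alone), and the list test passed downward with adjusted p = 3.85e-04, adjusted p = 0.603 with an estimated correlation, adjusted p = 0.0843 in the hyphen form, and adjusted p = 0.0610 without control 3. Their mean log2 CPM was 3.58, 1.75 and 4.30 in the 3 controls and 1.93 to 2.65 in the 4 survivors, so 1 control lay below every survivor. The smooth muscle list passed upward with 0 of 10 members called in edgeR (2 adjusted over the list alone, 5 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom), adjusted p = 0.00324 and adjusted p = 0.538 with an estimated correlation. TAGLN was at 0.98 ± 0.25 and ACTA2 at 0.86 ± 0.24. The mesothelial list passed likewise with 0 of 4 members called in edgeR (2 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom), adjusted p = 0.00883 and adjusted p = 0.535 with an estimated correlation. Its adjusted p was 0.232 in limma-voom, 0.354 with the animal as a random block and 0.0852 with regions 1 and 2 only. Survivor 4, with a list mean of 1.36 log2 CPM, lay among the controls (1.10 to 2.20) and apart from the other survivors (3.46 to 4.45). The call of 3 further upward lists was lost when 1 animal was left out. The transitional epithelium list (LGALS3 0.98 of 8 genes, 1 adjusted over the list alone) had adjusted p = 0.0217, 0.573 with an estimated correlation, and 0.0779 or 0.0741 without control 2 or survivor 4. The TGF-beta list (TGFB3 0.64 of 14 genes, 3 adjusted over the list alone) had adjusted p = 0.0171, 0.538 with an estimated correlation, and 0.102 or 0.105 without control 2 or survivor 2. The sterol list (SREBF1 0.83 of 12 genes, 2 adjusted over the list alone) had adjusted p = 0.0381, 0.603 with an estimated correlation, 0.274 in the underbar form, and 0.181, 0.102 or 0.127 without control 1, control 2 or survivor 2.

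Outside the lists that passed, PLAU (1.49) was higher and TIMP3 (-0.68) lower among 13 proteases and inhibitors, and CTSH (1.05) was higher and ETV5 (-0.81) lower among 11 type 2 cell genes. IL7R (-0.98), CR2 (-2.42), NDRG1 (-0.53) and BNIP3 (-0.66) were lower members of the T and NK cell, B and plasma cell and hypoxia lists. Of 22 collagen and matrix genes, 0 were called in edgeR (0 adjusted over the list alone), 5 had an unadjusted p under 0.05, and 1 passed in DESeq2 and 0 in limma-voom. The largest rises by the naming rule were in SERPINA3 (5.14), GPC5 (3.93), CLDN10 (3.35), PIP (3.19), CCL11, an eosinophil attractant (2.75), EDA2R (2.70), CCL2 (2.70) and MBL1, a mannose-binding lectin (2.59). The largest falls after PNMT were in FSTL4 (-2.77), TMPRSS9 (-2.63), CYP2A6 (-2.60), ABCC8 (-2.43), FGF10, a growth factor of lung mesenchyme (-2.34), SLC16A12 (-2.18) and HIF3A (-2.14). Without 1 animal, SERPINA3 was at 3.91 (survivor 3) or 5.77 (control 2), CR2 at -1.41 (control 1, adjusted p = 0.194) and CLDN10 at 4.06 (control 3, adjusted p = 0.104). MBL1 was at 3.47 without control 3, GPC5 at 4.56 without control 1 and FSTL4 at -3.57 without survivor 4. Of 36 named genes called in this comparison, 25 lost the call without some animal.

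Of the 29 lists, 9 passed upward and 2 downward, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 with fry (8 at an unadjusted p under 0.05). The count of genes was 2 and 0 in the hyphen and underbar label forms (2214 and 2383 at an unadjusted p under 0.05 in edgeR), where the 684 genes, picked from these same animals, had a median of 0.993 and 1.01 times their log2 fold change and standard errors 1.33 and 1.38 times as large with fewer animals, and 253, 172, 312, 394 or 346 without control 1, control 3 or survivor 1, 2 or 3. With control 2 left out, so that no animal is in both forms, 86.9% of 1608 and 86.3% of 1649 genes with an unadjusted p under 0.05 in 1 form had the same sign in the other (64.8% of all genes).

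Genes that changed in both irradiated groups numbered 618, of which 262 were higher and 356 lower in both. They include EDA2R, CDKN1A, CCL2, TREM2 and SERPINA3 among the higher and CLDN5, TIMP3, PNMT, IL7R and ABCC8 among the lower. If the lists were independent, 49.98 and 64.7 would be shared, and 50 simulations of unchanged groups that shared controls gave a mean of 0.02 and at most 1. Neither group was changed in these, so they cannot give the overlap of groups with unrelated changes against the same controls. That case was not simulated. Over all genes, the covariance of both sets of fold changes was 0.34, against a mean of 0.0770 in those simulations. Their correlation was 0.71, against a mean of 0.61 in those simulations, so shared controls alone gave a high correlation too. Both comparisons use the same 3 controls, which are too few to be divided between them. In 493 of the 618 genes the non-survivors lay farther from the controls, and the median ratio of survivor to non-survivor log2 fold changes was 0.71. Of these genes 233 also passed the test between non-survivors and survivors, and 229 of those were farther from control in non-survivors. Without control 1, 2 or 3, non-survivor 4, or survivor 1, 2 or 3, the count was 235, 350, 161, 410, 287, 373 or 304, and it was 2 and 0 in the hyphen and underbar label forms.

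The comparison of non-survivors with survivors asks what differs between irradiated animals that died and those that lived. Non-survivors had higher levels than survivors of some genes of stressed epithelium, macrophages, chemokines, p53 targets, collagens and proliferation, and lower levels of a few endothelial genes. In these lists 7 of 8, 6 of 15, 6 of 14, 11 of 19, 8 of 22 and 6 of 14 genes were higher and 3 of 13 endothelial genes lower, and with an estimated correlation no list passed (adjusted p = 0.175 to 0.304). SPP1 averaged 123 ± 40.5 CPM (SD, n = 4) in non-survivors and 10.2 ± 2.12 CPM (n = 4) in survivors, a log2 fold change of 3.59 ± 0.25 (SE, adjusted p = 3.48e-04). RRM2, a ribonucleotide reductase subunit used in DNA synthesis (ENSMMUG00000002057, chromosome 13, 10210687 to 10217331), averaged 30.6 ± 4.61 CPM (SD, n = 4) and 5.73 ± 2.09 CPM (n = 4), a log2 fold change of 2.43 ± 0.47 (SE, adjusted p = 0.00845). MS4A15 (ENSMMUG00000000017, chromosome 14, 13320604 to 13327838) averaged 0.292 ± 0.25 CPM (SD, n = 4) and 8.93 ± 5.4 CPM (n = 4), a log2 fold change of -4.98 (adjusted p = 0.00765). In edgeR, 2954 genes changed, 1596 higher and 1358 lower in non-survivors, and 784 of them by at least 2-fold.

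Of 8 genes of stressed or transitional epithelium, 7 were higher in non-survivors (7 adjusted over the list alone), with AREG at 2.90 ± 0.49, SFN at 2.86 ± 0.45 and KRT19 at 1.25 ± 0.25. The list test gave adjusted p = 2.14e-06, and adjusted p = 0.175 with an estimated correlation. Of 15 macrophage and monocyte genes, 6 were higher (8 adjusted over the list alone), with VSIG4 at 1.73 ± 0.22 and TREM2 at 1.48 ± 0.26, adjusted p = 1.05e-07 and adjusted p = 0.175 with an estimated correlation. Of 9 senescence-associated genes, 6 were higher (7 adjusted over the list alone), with IGFBP3 at 2.27 ± 0.34 and GDF15 at 1.86 ± 0.23, adjusted p = 2.00e-08 and adjusted p = 0.175 with an estimated correlation. Of 19 p53 targets, 11 were higher and XPC (-0.29) lower (12 and 1 adjusted over the list alone), with CDKN1A at 1.88 ± 0.23 and BAX at 1.13 ± 0.15, adjusted p = 1.39e-07 and adjusted p = 0.175 with an estimated correlation. Of 14 NF-kB genes, 6 were higher (7 adjusted over the list alone), with CCL2 at 2.35 ± 0.27 and IL6 at 2.26 ± 0.33, adjusted p = 2.37e-04 and adjusted p = 0.250 with an estimated correlation. Of 14 cell cycle genes, 6 were higher (14 adjusted over the list alone), with TYMS at 1.29 ± 0.29 and AURKB at 1.74 ± 0.42, adjusted p = 2.90e-07 and adjusted p = 0.304 with an estimated correlation.

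Of 22 collagen and matrix genes, 8 were higher and DCN (-0.79) lower (13 and 1 adjusted over the list alone), with THBS2 at 1.46 ± 0.24 and COL6A3 also among the higher, adjusted p = 8.49e-06 and adjusted p = 0.250 with an estimated correlation. Of 13 proteases and inhibitors, 7 were higher and TIMP3 (-1.01) lower (10 and 1 adjusted over the list alone), with PLAUR at 1.95 ± 0.25 and MMP3 at 4.57 ± 0.76, adjusted p = 1.08e-05 and adjusted p = 0.175 with an estimated correlation. The immediate early list had 4 of 8 genes higher, ATF3, JUNB, FOSB and EGR1 (6 adjusted over the list alone), with adjusted p = 0.00193, 0.250 with an estimated correlation, 0.0658 at 1 age and 0.0683 in the hyphen form. The NRF2 list had 4 of 8 genes higher, among them SLC7A11 (1.88), SRXN1 (1.18) and GCLC (0.66) (5 adjusted over the list alone), with adjusted p = 0.00322 and adjusted p = 0.229 with an estimated correlation. Of 13 endothelial genes, CLDN5 (-0.74), TEK (-0.64) and EGFL7 (-0.49) were lower (6 adjusted over the list alone), with adjusted p = 0.00287, 0.304 with an estimated correlation and 0.182 in the underbar form. The hypoxia list had 6 of 11 genes higher, with HK2 (1.84) and PGK1 (0.69), and ADM (-1.30) and NDRG1 (-0.75) lower (6 and 2 adjusted over the list alone), with adjusted p = 0.0277, 0.304 with an estimated correlation, 0.131 with age as a covariate, and 0.0698 without survivor 2. IL7R (-0.70) was the member called of the T and NK cell list (1 adjusted over the list alone), with adjusted p = 0.0277, 0.538 with an estimated correlation, 0.686 in the underbar form, and 0.137 or 0.0936 without non-survivor 2 or survivor 1. The ciliated list passed downward with 0 of 10 members called in edgeR, DESeq2 or limma-voom and 0 at an unadjusted p under 0.05, adjusted p = 0.0251 and adjusted p = 0.611 with an estimated correlation. Without non-survivor 3 or 4, or survivor 2 or 3, that p was 0.0519, 0.0818, 0.0599 or 0.0599, and in the hyphen form 0.121.

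Outside the lists that passed, 4 of 11 type 2 cell genes were higher in non-survivors, with CTSH (0.67), NAPSA (0.78) and LPCAT1 (0.61), and 3 of 9 type 1 cell genes lower, with EMP2 (-0.72) and CAV1 (-0.70). Of 14 TGF-beta genes 1 was higher and 3 lower, with SMAD6 (-1.33) and LTBP1 (-0.61), and the list did not pass (median 0.10, adjusted p = 0.824). AGT (1.44) was higher and ENPEP (-2.15) lower of 5 renin-angiotensin genes, and LMOD1 (-0.80) and MYLK (-0.52) were lower of 10 smooth muscle genes. Higher members were 2 of 10 B and plasma cell genes with MZB1 (1.73), 2 of 12 sterol genes with SREBF1 (0.87) and 2 of 8 complement genes. So was 1 gene each of the airway (KRT15, 3.08), mast cell (HDC, 2.49), interferon (RSAD2, 1.29), cartilage (ACAN, 2.25) and mesothelial lists. Adjusted over the list alone these counts were the same, except 3 higher in the TGF-beta list and 1 also lower in the mesothelial list. The largest rises after MMP3 by the naming rule were in CEACAM5 (4.35), the antimicrobial peptide gene DEFB1 (4.34), COMP (4.23), SLN (4.08), CLC, an eosinophil granule protein (3.86), LRRN4 (3.68) and GJB2 (3.66). After MS4A15 the lower genes were SLC6A4 (-4.40), SEC14L3 (-4.20), TMEM132B (-2.90), SPOCK1 (-2.79), SERPINB13 (-2.77), SEC14L4 (-2.70) and CRISPLD1 (-2.48). DEFB1, COMP and CLC averaged 115 ± 126, 20.9 ± 28.4 and 23.1 ± 27.5 CPM (SD, n = 4) in non-survivors, each with 1 high animal. Their log2 fold changes were 3.23 and 2.71 without non-survivor 1 and 2.56 without non-survivor 4, and that of CRISPLD1 was -1.53 without survivor 2 (adjusted p = 0.0920). COMP lost its call without survivor 2 (adjusted p = 0.0507). Moves of over 1.5 times away from 0 were MMP3 (5.48 without survivor 3), SLN (4.91 without survivor 2) and MZB1 (2.42 without survivor 4). So were SEC14L3 (-5.48), SEC14L4 (-3.29) and SERPINB13 (-3.88) without non-survivor 2, and SLC6A4 (-5.72) and TMEM132B (-3.69) without non-survivor 4. Of 69 named genes called in this comparison, 17 lost the call without some animal.

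Of the 29 lists, 11 passed upward and 3 downward, 0 with an estimated correlation (6 at an unadjusted p under 0.05), and fry passed 13. The count of genes was 1 and 5 in the hyphen and underbar label forms (with 1.09 and 0.918 times the log2 fold change of the 2954 genes, and standard errors 1.45 and 1.46 times as large), 16 with age at irradiation as a covariate, and 1 among animals of 1 age (0.976 and 1.00 times, and 1.32 and 1.23 times), as medians over genes picked from these same animals; without non-survivor 1 or 3, or survivor 1 or 2, it was 1687, 1881, 1707 or 1508. Of genes with an unadjusted p under 0.05 in 1 label form, 90.0% of 3822 and 92.0% of 2699 had the same sign in the other, where 72.3% of all genes did.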

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

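The tests of age, of unequal change among endothelial members, of single controls and ages in the cell cycle list, and of read share between label forms were chosen after the results were seen.

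In non-survivors 5917 genes differed from controls. Of 35 splits of the 7 animals only the real one gave as many. The highest other gave 2780, in the split that puts non-survivor 2 with the controls. Chance is thus unlikely for this count but not excluded, since 1 of 35 is the smallest share that these splits can give. Removing each animal's trend with gene span, which RNA integrity could cause, left 88.3% of these genes past the threshold in the same direction. The span runs from gene start to gene end, not along the transcript, and the trend was small (median size 0.0215 on the log2 scale). No RNA integrity values were used, so this says little about RNA integrity itself. A shift of reads to the 3 abundant short genes annotated as miRNA would turn the fold changes around between label forms, whose non-survivors lay on either side of the controls in that share, but with control 2, which is in both forms, left out, they correlated at 0.603 over all genes, and at 0.518 to 0.677 between single non-survivors of each form (with the share as a covariate 100% of the genes kept their sign, which decides nothing because the share hardly differs by group). Mean ages at irradiation on the labels were 5.26 years in survivors, 4.51 in non-survivors and 2.69 in controls. What this age marks for the unirradiated controls is not known here. An age effect that runs 1 way would put survivors at least as far from controls, yet 2439 genes lay farther in non-survivors past the threshold (4 opposite). Both comparisons share the non-survivors, which favours 1 direction, and age at tissue collection is not in the labels. These genes therefore argue only against a 1-way effect of age at irradiation. For the other 3478 genes age and irradiation cannot be told apart because every control was younger by the labels. The choice of affected regions stays open for all.

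The endothelial list was lower in non-survivors, with a median log2 fold change of -0.66 (adjusted p = 0.190 with an estimated correlation). A lower share of endothelial cells alone would lower its members alike if no other cells expressed them. They differed by more than their standard errors (Cochran's Q 76.7 over 13 members, 12 degrees of freedom, p = 1.73e-11, taking members as independent). This cannot decide, because expression in other cells, which was not measured, would also make the falls unequal. A lower share of endothelial cells, loss of some vessel types, or lower expression per cell may remain. So may age and the choice of affected regions, which the design confounds with irradiation.

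The cell cycle list was lower in survivors than in controls, and this rests on few controls. The adjusted p of the list was 0.00418, 4.58e-23 or 0.0610 without control 1, 2 or 3, and an exact two-sided permutation test of the list means gave p = 0.257, so a single control animal may decide the call. Survivors of 5.76 years lay 0.26 (log2) above those of 4.76 years, 2 against 2 animals, too few to weigh age as the cause. Non-survivors lay above survivors by a median of 1.44 over members (exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.304 with an estimated correlation), with each non-survivor at 3.27 or more and each survivor at 2.65 or less in mean log2 CPM.

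Chance is also unlikely, though not excluded by 35 splits, for the 684 genes of survivors against controls, where the highest of the other 34 splits gave 42. The same holds for the 2954 genes between the irradiated groups, where the highest other gave 88. For the number of gene lists that passed, chance cannot be called unlikely. The 11 lists of non-survivors against controls were reached or passed in 14 of 35 splits (highest other 16), the 11 lists of survivors against controls in 9 of 35 (highest other 18), and the 14 lists between irradiated groups in 6 of 35 (highest other 16).

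Single animals stood apart from their group in 6 of 142 groups tested, where chance alone gives 7.1. Survivor 1 had a mean log2 CPM of 7.94 over the collagen and matrix list, below 8.22 to 8.27 in the other survivors. Non-survivor 2 had 3.32 over the ciliated cell list, above 0.419 to 0.848 in the others. In single libraries its regions 1, 2 and 3 were at 1.74, 4.85 and 0.924, so region 2 stood out. Regions also differed in control 1 (1.34 and 3.46), control 2 (2.03 and 4.29) and control 3 (2.86 and 3.83). In survivors 1, 2 and 3, 1 region was also high, at 3.49, 4.34 and 4.19, against 0.813 to 1.53 in their other regions. Survivor 4 was at 0.849, 2.32 and 0.822, and the regions of non-survivors 1, 3 and 4 lay at 0.501 to 1.52. The level of this list thus varied with the region sampled, and calls of the list may depend on it. SERPINA3 was at 9.27 log2 CPM in survivor 3 and at 6.24 to 6.75 in the other survivors. MS4A15 was at 0.297 in survivor 3 and at 3.37 to 3.77 in the others. FGF10 was at 1.00 in non-survivor 2 and at -0.596 to -0.387 in the others. SERPINB13 was at 2.82 in survivor 4 and at 3.53 to 3.61 in the others.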

How the results depend on the processing

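The exact permutation of list means, protein-coding genes alone and leaving out region 2 of non-survivor 2 were chosen after the results were seen.

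For non-survivors against controls, the 5917 genes became 2132 and 2134 within the hyphen and underbar label forms, which hold fewer animals, and 4327 to 6077 when 1 animal was left out. The other settings gave 5179 to 8121.

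For survivors against controls, the 684 genes became 1734 with DESeq2, 1345 and 1475 in limma-voom with the animal as a random block, without and with a term for label form, 3197 with 30 libraries taken as independent, which overstates replication, and 2 and 0 within the label forms. Leaving out 1 animal gave 172 to 751. For genes changed in both irradiated groups (618), the same settings gave 1369, 1066, 1145, 2527, 2 and 0, and leaving out 1 animal 161 to 664.

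For non-survivors against survivors, the 2954 genes became 4651 and 4635 with the animal as a random block, 7051 with independent libraries, 1 and 5 within the label forms, 16 with age as a covariate and 1 at a single age. Leaving out 1 animal gave 1508 to 3304. With age as a covariate 3744 genes had an unadjusted p under 0.05, and at a single age 4044, and the 2954 genes had a median of 0.976 and 1.00 times their log2 fold change with standard errors 1.32 and 1.23 times as large. The cause of the differences was not tested where no reason is given. In the self-test, which had fewer changed genes and edgeR's own dispersions, DESeq2 made 20.4% to 24.9% false calls. That rate need not hold for these counts.

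Gene lists passing, 11, 11 and 14 in the 3 comparisons, became 0, 0 and 0 with an estimated correlation or exact permutation of list means (16, 2 and 11 at p = 0.0286, the smallest that permutation can give). In non-survivors against controls the hyphen form gave 19 and fry 17. In survivors against controls the underbar form gave 17, limma-voom 7, the animal as a random block 4 and 4, independent libraries 7 and fry 0. The cause was not tested.

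Blocking on the replicate number gave 5642, 489 and 2781 genes, but the labels do not say that the numbers pair animals. The 10 same-number pairs correlated at -0.0575 to 0.174 and other pairs at -0.156 to 0.081. Yet 9 of 11 animals correlated best with one of their own number, so a pairing by number stays open. Upper-quartile scaling shifted the median of all genes by at most 0.041 on the log2 scale and made 47.2% of the calls in non-survivors against controls higher, against 52.4%. In survivors against controls it made 37.5% higher, against 41.2%, and in non-survivors against survivors 49.1%, against 54.0%, so the balance of directions depends on the scaling. The correlation of regions within an animal was 0.27 without the filter, which adds genes of few counts. Of 1144 list results under alternatives, 984 kept direction and side of the threshold, 160 lost the call and 0 reversed. Of 6686 results for named genes, 5664 kept both, 1010 lost the call, 12 gained it and 0 reversed.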

Other observations

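The endothelial subtype, glucocorticoid and clock lists were written after the data had been examined but before their values were computed, and in this part only the exact permutation of list means and the capillary test against arterial genes were chosen after list results had been seen.

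Endothelial genes of different vessels moved apart in non-survivors. Of 4 general capillary genes, 3 were lower than in controls, ADGRL2 (-1.14), GPIHBP1, which holds lipoprotein lipase on capillaries (-2.61), and FCN3 (-0.95), with a list median of -1.04 (adjusted p = 0.0482 over these lists, adjusted p = 0.157 with an estimated correlation). Of 6 venous and systemic genes, 5 were higher, among them the adhesion molecule SELE (5.32), COL15A1 (2.54) and PLVAP, of fenestrated endothelium (1.47), with a median of 1.69 (adjusted p = 0.00255, and 0.108 with an estimated correlation). Of 5 arterial genes, EFNB2 (-1.32), HEY1 (-1.48) and BMX (-1.06) were lower (median -1.06, adjusted p = 0.00255, and 0.157 with an estimated correlation), and of 4 aerocyte genes HPGD (-1.55), SOSTDC1 (-1.68) and TBX2 (-0.56) were lower (median -1.05, adjusted p = 0.0407, and 0.182 with an estimated correlation). The 4 lymphatic genes had a median of 0.32 (adjusted p = 0.669). Exact two-sided permutation tests of the list means gave p = 0.0286, the smallest they can give, for the capillary, venous and arterial lists, and p = 0.0857 for aerocytes. In survivors against controls the venous list was higher with 0 of 6 genes called (median 0.81, adjusted p = 0.0120, and 0.248 with an estimated correlation) and the arterial list lower with 2 of 5 called (median -0.78, adjusted p = 0.0120, and 0.250 with an estimated correlation), but the aerocyte list had a median of 0.38 (adjusted p = 0.881) and the capillary list one of -0.56 (adjusted p = 0.365). Exact permutation gave p = 0.0286 for the venous, 0.257 for the arterial, 0.0571 for the aerocyte and 0.771 for the capillary list there, and 2 of 5 arterial genes had fold changes above 0. Leaving out 1 animal moved SELE to 4.62 (non-survivor 3) and SOSTDC1 to -2.58 (non-survivor 4) in non-survivors. A hypothesis of capillary loss predicts that capillary genes fall more than those of other vessels. In non-survivors the capillary median minus the venous median was -2.73, but the arterial median (-1.06) was as low as the capillary one (-1.04), and exact permutation of the difference of those 2 list means gave p = 0.714. The hypothesis stays open, as does activation of the remaining endothelium, which also raises SELE and may give the same difference from venous genes.

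Lower glucocorticoid signalling in irradiated lungs was tested as a hypothesis with 8 known targets. The list was lower in both irradiated groups, with unadjusted p = 0.00638 in non-survivors, the larger of the 2, and adjusted p = 0.0170 and 1.27e-04 in non-survivors and survivors. With an estimated correlation neither passed, with adjusted p = 0.431 and 0.250 (unadjusted p = 0.269 and 0.0936), and exact permutation gave p = 0.0286 and 0.0571. In non-survivors ZBTB16 (-3.66), TSC22D3 (-2.31) and MAOA (-1.38) were among 6 lower members and SGK1 (1.82) was higher. In survivors MAOA (-0.80) was lower and SGK1 (0.92) higher, and survivor 4, with a list mean of 7.03 log2 CPM, lay near the controls (7.13 to 7.46) and apart from the other survivors (5.44 to 5.86). Stress at the time of tissue collection and steroid treatment, neither of which is in the labels, may also change these genes.

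A different time of day at tissue collection would move the morning and evening arms of the circadian clock in opposite directions. The number of comparisons with both arms past 0.05 in opposite directions was 0, with unadjusted p = 0.236 and 0.578 for the arms in non-survivors against controls. The criterion written beforehand counts this against such a difference, but it was too weak, since a p that misses the threshold sets no bound: evening arm means ran from 3.25 to 5.02 log2 CPM in non-survivors and from 4.26 to 4.75 in controls, so time of day stays open.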
